A study of Caenorhabditis elegans with 6 samples.

How the data were processed

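Whole Caenorhabditis elegans, labelled as adults, of the wild-type strain N2 and of the mutant bcf-1(ylf1) were profiled by RNA sequencing while feeding on Escherichia coli OP50, the standard laboratory food bacterium. There were 3 libraries per genotype and 6 in all. Per the series design text, the 3 replicates of each genotype were generated, collected and processed independently, so the spread between libraries includes biological variation. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal RNA-seq kit for Illumina sequencing. The genotype of each library was taken from its label, and each column of the expression table was matched to a library by the label it carries.

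The authors deposited 1 table with a value per gene and library, read here as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). Neither the header nor the labels name the unit. The values are not whole numbers, values of genes above 0 in a single library fall with transcript length (Spearman correlations from -0.62 to -0.28), and the columns sum to between 659249 and 687573 rather than to the fixed total of TPM, so a length-normalised unit was inferred. TPM columns from which rows were left out cannot be excluded. Reads were handled with fastp and the genome build was WBcel235, per the submitters' processing notes. The aligner, the quantifier, the annotation release and any use of strand are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical gene copies may be divided between them in an unknown way. The table held 20894 rows, of which 909 were unnamed loci called newGene and 1599 were at 0 in every library. RefSeq locus tags of the WBcel235 annotation table matched 19959 rows and gave gene symbols and positions, and 26 tagged rows were left unmatched. None of the 12 protein genes of the mitochondrial genome had a row, so the list of mitochondrially encoded genes had 0 tested members. The sequencing depth is unknown. In genes where a step per read could be sought, 21.3% to 39.4% of values times length fell within 10% of the most common one, which 0 of 1000 shuffles of the lengths reached in any library, but the rest did not, so whole reads could not be recovered and no counting interval is given.

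Before the data were examined, a count-based test was planned in case the table held counts, with limma on log2 values as the stated choice for normalised values. The table held normalised values, so limma 3.58.1 in R 4.3.3 was used. Values were transformed as log2(FPKM + 1), genes with at least 1 FPKM in at least 3 libraries were kept (13576 genes), and a model with genotype as the only term was fitted with a mean-variance trend in the empirical Bayes step. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Every adjusted p of a single gene below is from this limma fit. Log2 changes are mutant minus N2 on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of mean FPKM. Counts of genes changed at least 2-fold instead took changes of at least 1 log2 unit on the log2(FPKM + 1) scale. Means are given ± SD over 3 libraries.

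The fixed gene lists, 36 in all, were compiled from general knowledge of the worm before the data were examined. They cover the targeted gene and its neighbour, stress responses, defence, detoxification, lipid and haem metabolism, yolk, cuticle, ribosomes, histones, germline, sperm, oocytes, embryos, and markers of intestine, pharynx, muscle, neurons and hypodermis. Lists defined by a symbol pattern, such as the C-type lectins, took every tested gene with that pattern. The 34 lists with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over these lists, and again with a correlation estimated from the data. Camera compares a list with the other tested genes. Fry from limma, planned beside camera, asks whether the genes of a list change in 1 direction, without comparing them with other genes. Genes were named by a rule fixed beforehand: bcf-1 and its paralogue gfi-1; the 10 largest rises and 10 largest falls among genes with an adjusted p under the threshold, a mean of at least 1 FPKM and no overlap between the genotypes; up to 4 members with the smallest p in each list; and hsp-6, hsp-60, hsp-4, gst-4, sod-3 and the vitellogenins. Other genes named to spell out a small count were chosen after their values were seen, and the text says so. The share of called genes per chromosome was compared with that of the other tested genes by two-sided Fisher's exact tests, adjusted over 6 chromosomes.

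The fit was tested on simulated data: values for the 13576 genes of the mutant against N2 comparison were drawn around the N2 means with the residual spread of each gene, with 200 genes above 1 FPKM in N2 changed per round over 5 rounds. Of genes changed 2-fold, 50.4% were called, and of genes changed 4-fold, 86.6%. Of the calls, 2.97% were false. The simulation drew noise independently for each gene and had no overall shift, and it changed few genes. In the data 49.6% of tested genes were called, so these shares do not carry over to the real comparison. The alternatives planned beforehand were no filter on low values, a filter on the mean over libraries, a pseudocount of 0.1, a threshold of 0.01, the replicate number as a block, leaving out each library in turn, and the estimated correlation in camera. After the data were examined, median-ratio scaling and quantile normalisation were added, because the median change of all tested genes lay above 0. Ranges of camera p-values over the other alternatives leave out the estimated correlation, which is given beside them. Leaving out a library also drops genes that reach 1 FPKM only in the 3 libraries of its genotype. Counts of rises without a mutant library, and of falls without an N2 library, are therefore partly fixed by the filter. Alternatives that need counts were not run. Figures were drawn with matplotlib.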

Results

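RNA was measured in whole animals, labelled as adults, of 2 genotypes of the nematode C. elegans, the wild-type strain N2 and bcf-1(ylf1), a mutant of the gene that encodes BCF-1, which the series title describes as a glycosylated protein of the intestine that binds bacteria. Each genotype had 3 independent libraries. The deposited values, read as FPKM, summed to between 659249 and 687573 per library, and the depth behind them is unknown. Median FPKM over tested genes was 10.1 to 12.01 in the N2 libraries and 12.4 to 13.6 in the mutant libraries, and the 20 most abundant genes held 9.28% to 11.84% of each library's total. Across genes, which are not independent replicates, Spearman correlations were 0.972 to 0.991 between libraries of the same genotype and 0.875 to 0.901 between genotypes. The first principal component held 80.4% of the variance and separated the genotypes. The second held 8.79%, and on it N2 replicate 1 lay at 28.9 and the other N2 libraries at -14.9 and -13.4.

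The first comparison asked whether the targeted gene differed in the mutant. bcf-1 (F57F4.4; chromosome V, 6401379 to 6408783, WBcel235) fell from 428 ± 64.1 FPKM in N2 to 65.3 ± 6.20 FPKM in the mutant (SD, n = 3 each), a 6.56-fold lower mean. The N2 libraries lay at 374, 412 and 499 FPKM and the mutant libraries at 63.7, 72.1 and 60.01 FPKM. Its neighbour and paralogue gfi-1 (F57F4.3; chromosome V, 6392537 to 6399931) fell from 440 ± 71.7 to 73.7 ± 5.71 FPKM, 5.97-fold lower. In limma the log2 changes were -2.69 (SE 0.14, adjusted p = 3.6e-06) for bcf-1 and -2.55 (SE 0.14, adjusted p = 5.0e-06) for gfi-1, larger than the spread between replicates. Both members of the list of the targeted gene and its paralogue fell, also when adjusted over the list alone. The ratio of gfi-1 to bcf-1 was 1.01 to 1.04 in the N2 libraries and 1.11 to 1.15 in the mutant libraries, and how reads of these similar genes were divided is not given in the sources used here, so the value of each gene alone is uncertain. Their sum fell 6.25-fold. What the ylf1 allele changes in the gene is not stated in the labels.

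Genes around the locus moved in both directions. Chosen after their values were seen, F57F4.1, next to gfi-1, had a log2 change of 0.77, cht-6 of 0.70 and urb-1 of -0.09 (limma adjusted p = 0.0106, 0.00777 and 0.676). With bcf-1 and gfi-1 left out, the 26 tested genes within 100 kb of bcf-1 had a median log2 change of -0.0097, with 7 higher and 5 lower (46.2% called against 49.1% elsewhere, Fisher's exact test, two-sided, p = 0.846). The largest fall among them was of alh-4, also chosen after its value was seen, with a log2 change of -1.80. Within 1 Mb, 51.7% of 269 tested genes were called against 49.03% elsewhere (Fisher's exact test, two-sided, p = 0.423).

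**Figure D1:**
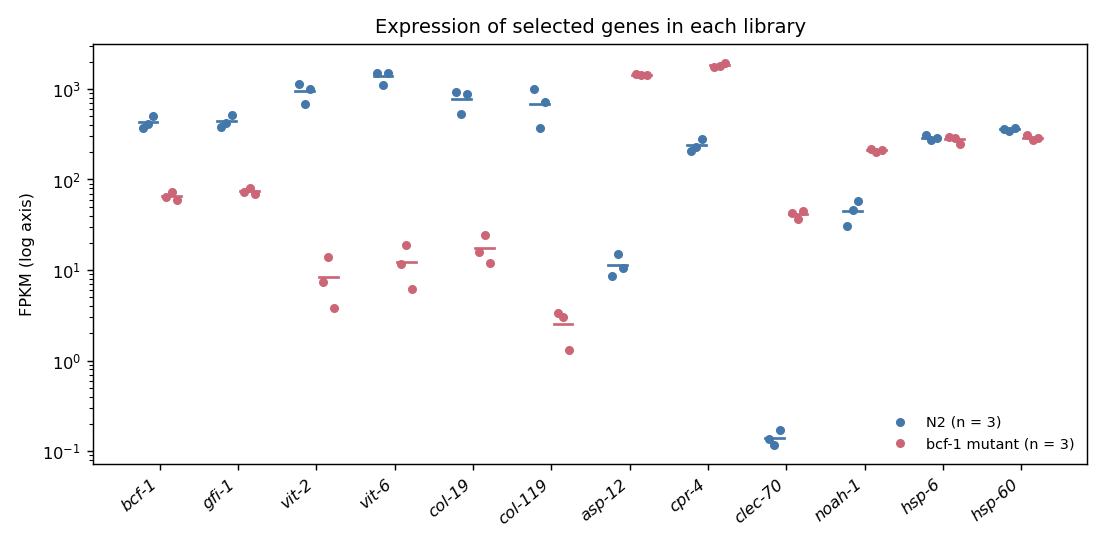
FPKM on a log axis of 12 genes in each of the 3 N2 libraries (blue) and 3 bcf-1 mutant libraries (red), with horizontal lines at the means. bcf-1 lies at 374 to 499 FPKM in N2 and 60.01 to 72.1 FPKM in the mutant, while hsp-6 overlaps between the genotypes.

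The second comparison asked which transcripts differed between the genotypes. On the log2(FPKM + 1) scale, the largest rises were of asp-12, an aspartyl protease gene, from 11.43 ± 3.32 to 1436 ± 24.7 FPKM (126-fold), and of the C-type lectin gene clec-70, from 0.142 ± 0.0269 to 41.3 ± 4.36 FPKM (291-fold). Next came ugt-18, ech-9, idpp-1, dod-21, mltn-1, K10D3.4, cld-1 and hrg-2, with log2 changes between 3.96 and 4.70. On that scale the largest falls were of the cuticle collagen gene col-119, from 688 ± 311 to 2.57 ± 1.105 FPKM (268-fold lower), and of the yolk protein genes vit-5, vit-4, vit-6, vit-3 and vit-2. The collagen genes col-8, col-62, col-7 and col-19 completed the 10 largest falls, with log2 changes of -6.76, -6.64, -6.55 and -5.42. By ratio of means the order differs, with clec-70 above asp-12 and col-8 (355-fold lower) above col-119. All 20 had adjusted p-values of at most 1.44e-05 in limma.

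By limma, 6738 of 13576 tested genes (49.6%) passed the threshold, 4703 higher and 2035 lower in the mutant. Of these, 1546 and 917 changed at least 2-fold on the log2(FPKM + 1) scale, which misses some low genes. The groups did not overlap in 58.4% of tested genes, against 10% by chance. The median log2 change of all tested genes was 0.24. It was 0.0017 after median-ratio scaling, which called 3065 genes higher and 3096 lower, and 0.072 after quantile normalisation, which called 3255 higher and 2803 lower, so the excess of rises depends on the scaling. For this reason the medians of lists called by camera are given below also relative to 0.24. Some lists with a median above 0 lay below that level: fasting response (-0.03 relative to it), body wall muscle (-0.11), mitochondrial unfolded protein response (-0.21) and N-glycosylation (-0.22). Without mutant replicate 1, 2877 genes rose, and without mutant replicate 3, 3002. Of the unnamed newGene loci, 321 were tested and 230 were called.

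**Figure D2:**
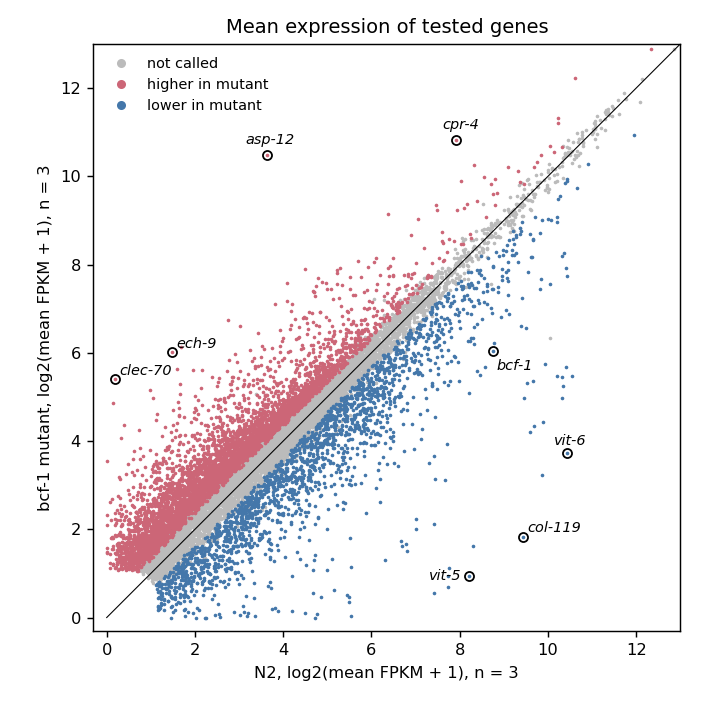
Mean expression of the 13576 tested genes as log2(mean FPKM + 1), N2 on the horizontal and bcf-1 mutant on the vertical axis (n = 3 libraries each). Red genes were called higher and blue genes lower in the mutant by limma, grey genes were not called, and the line marks equal means. Before any rescaling, 4703 genes were higher and 2035 lower.

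Vitellogenin transcripts were low in the mutant. All 6 vitellogenin genes, which encode yolk proteins made in the intestine of adult hermaphrodites, fell, with a median log2 change of -6.81 (-7.04 relative to all genes). vit-2 dropped from 940 ± 228 to 8.43 ± 5.19 FPKM, vit-6 from 1377 ± 235.5 to 12.2 ± 6.28 FPKM and vit-1 from 109 ± 21.5 to 2.19 ± 0.253 FPKM. vit-3, vit-4 and vit-5 are close copies, so the value of each is uncertain. The camera adjusted p was 2.4e-09, and the adjusted p = 0.524 with an estimated correlation. Adjusted over the list alone, all 6 fell as well.

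The cuticle collagen list took genes named col, rol, sqt, bli or dpy, some of which do not encode collagens. Of 154 tested, 72 fell, all of them col genes, and 39 rose (73 and 42 adjusted over the list alone). The median log2 change was -0.28 and the mean -0.96 (median -0.52 relative to all genes), and the median ran from -0.51 to -0.06 over the alternatives. It was -0.27, -0.06 and -0.11 without N2 replicates 1, 2 and 3, where 146, 147 and 146 genes of the list passed the filter. Camera gave an adjusted p of 1.1e-08, and the adjusted p = 0.524 with an estimated correlation. col-19, a collagen of the adult cuticle, fell from 774 ± 220 to 17.3 ± 6.46 FPKM, col-181 from 1286 ± 285 to 43.0 ± 1.41 FPKM, col-106 from 808 ± 160 to 39.9 ± 1.06 FPKM, col-184 from 704 ± 161 to 30.5 ± 1.42 FPKM and col-137 from 128 ± 15.03 to 3.03 ± 0.498 FPKM. The list of hypodermis and adult cuticle genes went both ways, with 10 of 18 higher and 5 lower, also when adjusted over the list alone. Its median was 0.89 and its mean -0.02 (camera adjusted p = 0.634). In it dpy-10, a collagen gene, rose from 17.3 ± 4.37 to 136 ± 11.3 FPKM, while col-7, col-19, col-62, pah-1 and hpd-1 fell, the last pair chosen after their values were seen.

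Of 24 oocyte and eggshell genes, 5 fell (2 adjusted over the list alone): perm-2, perm-4, cpg-3, nos-2 and puf-5, the last chosen after its values were seen. perm-2 fell from 111 ± 42.4 to 25.2 ± 1.97 FPKM. The median log2 change was -0.49 (-0.73 relative to all genes; -0.09 without N2 replicate 1, where 4 fell and 1 rose, and -0.83 without N2 replicate 2), with a camera adjusted p of 0.00058 and an adjusted p = 0.782 with an estimated correlation. The count was 14 without N2 replicate 2, 3 without mutant replicate 1, 2 without mutant replicate 2 and 11 after median-ratio scaling.

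Those sperm and germline genes that passed the threshold were higher in the mutant. Of 93 major sperm protein and sperm genes, 33 rose and 0 fell, among them 24 of 32 spe genes and 3 of 30 msp genes, a split made after the values were seen (32 rose adjusted over the list alone; median 0.42, 0.18 relative to all genes, 0.16 to 0.56 over the alternatives). Across all 13576 tested genes 4703 rose, a share close to that of the sperm list, and 2035 fell. After median-ratio scaling 3 genes of the list fell and after quantile normalisation 2. spe-44, a regulator of sperm gene expression, rose from 5.16 ± 1.698 to 17.3 ± 2.93 FPKM, spe-41 from 5.599 ± 1.34 to 15.1 ± 1.99 FPKM, spe-19 from 1.39 ± 0.485 to 5.69 ± 0.0716 FPKM and spe-5 from 3.45 ± 0.498 to 9.65 ± 1.15 FPKM. Camera gave an adjusted p of 0.0479 for the sperm list, 0.404 without N2 replicate 2 and 0.0607 without mutant replicate 3 (0.000956 to 0.404 over the other alternatives), and the adjusted p = 0.784 with an estimated correlation. Of 30 germline genes, 13 rose and 0 fell (12 adjusted over the list alone; median 0.51, 0.28 relative to all genes, 0.27 to 0.79 over the alternatives). fog-3, needed for the sperm fate, rose from 1.33 ± 0.176 to 7.74 ± 1.47 FPKM, fog-1 from 2.77 ± 0.654 to 6.40 ± 1.05 FPKM, and syp-1 and syp-4 of the synaptonemal complex by 0.89 and 0.97 log2 units. For the germline list the camera adjusted p was 0.0307 and, without N2 replicate 2, 0.175 (0.000462 to 0.175 over the other alternatives), and the adjusted p = 0.784 with an estimated correlation. The count of rises was 26 without N2 replicate 1, 8 without N2 replicate 2, 8 without mutant replicate 1 and 8 after median-ratio scaling.

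Of 62 histone genes, 38 rose and 1 fell (his-40, chosen after its values were seen; 38 and 2 adjusted over the list alone), with a median of 0.61 (0.37 relative to all genes, 0.31 to 0.79 over the alternatives). his-24 rose from 32.8 ± 3.46 to 78.2 ± 8.61 FPKM and his-13 from 5.07 ± 0.671 to 15.1 ± 2.48 FPKM, and his-9 and his-25 by 1.07 and 0.96 log2 units. Most core histone genes have near-identical copies and their values are uncertain. Without N2 replicate 2 the count of rises was 17, without mutant replicate 2 or 3 it was 18, after median-ratio scaling 12 and after quantile normalisation 8. The camera adjusted p of 0.0186 became 0.294 without N2 replicate 1, 0.0661 without N2 replicate 2, 0.0579 without mutant replicate 2 and 0.139 after quantile normalisation (0.000224 to 0.294 over the other alternatives), and the adjusted p = 0.784 with an estimated correlation. The 6 tested early embryonic genes included 1 that rose, elt-1, from 3.38 ± 0.501 to 9.97 ± 0.447 FPKM (1 adjusted over the list alone; camera adjusted p = 0.497). For hlh-1, nhr-25 and pha-4 the limma adjusted p-values were 0.113, 0.121 and 0.0929.

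Most pharynx genes tested were higher in the mutant. Of 19 pharynx genes, 15 rose and 0 fell, also when adjusted over the list alone, with a median of 1.85 (1.61 relative to all genes). Without mutant replicate 2, 14 rose and 1 fell. myo-1, a pharyngeal myosin gene, rose from 9.12 ± 1.88 to 57.6 ± 2.94 FPKM, the troponin genes tni-4 from 18.6 ± 1.12 to 78.0 ± 3.64 FPKM and tnc-2 from 9.22 ± 0.708 to 49.1 ± 10.6 FPKM, and the transcription factor gene peb-1 from 1.73 ± 0.682 to 17.5 ± 2.80 FPKM. The camera adjusted p was 0.00033, and the adjusted p = 0.528 with an estimated correlation. Among other tissues, 9 of 25 body wall muscle genes rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.544, and 0.0195 after quantile normalisation and 0.869 with an estimated correlation, with 0.0195 to 0.757 over the other alternatives). The list median of 0.13 was 0.03 without N2 replicate 1 and 0.23 without mutant replicate 3, and it turned to -0.13 after median-ratio scaling, where 6 rose and 3 fell, and without N2 replicate 1 there were 3 falls as well. The share of muscle genes that rose was close to the 4703 of 13576 among all tested genes, and their median was -0.11 relative to all genes. unc-22, dys-1 and tni-3 rose by 1.45, 1.08 and 1.15 log2 units, and unc-54, the main body wall myosin gene, from 459 ± 60.2 to 787 ± 69.1 FPKM. Of 26 neuronal genes, 11 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.158, 0.0370 without a filter and 0.782 with an estimated correlation, with 0.0370 to 0.640 over the other alternatives). The count was 6 without mutant replicate 1, 7 without mutant replicate 2 or 3, 5 after median-ratio scaling and 3 after quantile normalisation, with 2 falls under each scaling. unc-13, unc-17, egl-30 and cat-2 rose by 0.86, 0.89, 0.54 and 0.65 log2 units. cat-2 was low, at 0.170 to 0.546 FPKM in N2, and its mean rose 3.21-fold, so its log2 change is understated. The calls of egl-30 after median-ratio scaling and of cat-2 after quantile normalisation were lost.

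Intestinal genes moved in both directions. Of 22 intestine markers, 11 fell and 3 rose (13 and 4 adjusted over the list alone), with a median of -0.40 (-0.64 relative to all genes, -0.66 to -0.32 over the alternatives), a camera adjusted p of 0.00080 and an adjusted p = 0.524 with an estimated correlation. The intermediate filament genes ifb-2, ifc-2 and ifp-1 of the intestine fell, ifb-2 from 428 ± 20.98 to 175 ± 3.39 FPKM. The rises were of cpr-1, a cathepsin B-like protease gene, from 177 ± 44.1 to 648 ± 12.59 FPKM, and of asp-1 and let-413, chosen after their values were seen. The count of rises was 1 without N2 replicate 1 or 2 or mutant replicate 1, and 1 after median-ratio scaling. Of 18 genes of the asp and cpr protease families, 12 rose and 4 fell, also when adjusted over the list alone, with a median of 0.64 (0.40 relative to all genes, 0.41 to 0.80 over the alternatives), a camera adjusted p of 0.194, 0.0201 after quantile normalisation and 0.782 with an estimated correlation (0.0201 to 0.573 over the other alternatives). cpr-4 rose from 239 ± 38.5 to 1824 ± 94.8 FPKM, cpr-5 from 320 ± 46.0 to 1217 ± 113 FPKM and cpr-8 from 10.5 ± 0.447 to 40.6 ± 5.42 FPKM. The falls, chosen after their values were seen, were of cpr-6, asp-4, asp-13 and asp-14.

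Genes of fat breakdown fell more often than they rose. Of 45 genes of lipid breakdown and beta oxidation, 27 fell and 8 rose (30 and 8 adjusted over the list alone), with a median of -0.85 (-1.08 relative to all genes), a camera adjusted p of 1.1e-08 and an adjusted p = 0.524 with an estimated correlation. lipl-2, a lysosomal lipase gene, fell from 58.2 ± 3.24 to 4.16 ± 0.439 FPKM, acdh-2, an acyl-CoA dehydrogenase gene, from 72.4 ± 10.9 to 5.11 ± 1.24 FPKM and the peroxisomal oxidase gene acox-3 from 88.5 ± 11.3 to 17.6 ± 2.84 FPKM, while acox-1.5 rose from 37.4 ± 5.91 to 151 ± 7.73 FPKM. After quantile normalisation 5 rose. Of 28 genes of fat synthesis and desaturation, 9 fell and 4 rose (8 and 4 adjusted over the list alone; median -0.15, -0.38 relative to all genes, -0.41 to -0.02 over the alternatives, the latter after quantile normalisation, where 7 fell and 5 rose). The desaturase gene fat-7 fell from 99.7 ± 14.3 to 31.6 ± 1.74 FPKM and the lipid regulator sbp-1 from 22.3 ± 1.095 to 10.1 ± 0.547 FPKM, while the fatty acid synthase gene fasn-1 rose from 33.9 ± 2.84 to 82.4 ± 5.89 FPKM, as did elo-4, and fat-5 and nhr-49, both chosen after their values were seen. With camera the adjusted p was 0.0109, 0.895 after quantile normalisation (0.00307 to 0.895 over the other alternatives) and the adjusted p = 0.524 with an estimated correlation. After median-ratio scaling 14 fell. Of 20 fasting response genes, 7 fell and 6 rose, also when adjusted over the list alone (camera adjusted p = 0.291), among them lipl-1 and lipl-5 with falls of 4.65-fold and 2.62-fold and asah-1 with a 3.02-fold rise. Their median of 0.21 was 0.07 without mutant replicate 2 and turned to -0.04 after median-ratio scaling and -0.02 after quantile normalisation.

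Of 17 genes of the propionate and vitamin B12 response, 5 fell and 3 rose, also when adjusted over the list alone (median -0.16, -0.40 relative to all genes, -0.41 to -0.06 over the alternatives). hach-1, hphd-1 and alh-8 of the propionate shunt fell, hach-1 from 790 ± 57.4 to 289 ± 18.8 FPKM, and metr-1, which encodes methionine synthase, rose from 113 ± 2.87 to 214 ± 16.8 FPKM. The others called, chosen after their values were seen, were acdh-1 and nhr-68, which fell, and mthf-1 and pcca-1, which rose. The camera adjusted p of 0.0479 became 0.0994 without N2 replicate 2, 0.0575, 0.0913 and 0.0607 without mutant replicates 1, 2 and 3, and 0.719 after quantile normalisation (0.0150 to 0.719 over the other alternatives), and the adjusted p = 0.782 with an estimated correlation. After median-ratio scaling 9 fell and 1 rose. Of 16 iron and haem genes, 5 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.479). hrg-2, which is induced when haem is low, rose from 0.313 ± 0.186 to 19.6 ± 3.86 FPKM and hrg-7 from 131 ± 19.6 to 519 ± 70.04 FPKM, while hrg-5 and hrg-6 fell 6.34-fold and 4.19-fold. Chosen after their values were seen, hrg-3, hrg-4 and ftn-1 also rose and smf-1 and smf-3 fell. The count of rises was 2 with any of the mutant replicates 1, 2 or 3 left out and 3 after median-ratio scaling, and the count of falls was 2 without N2 replicate 2.

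Detoxification genes fell more often than they rose. Of 33 glutathione S-transferase genes, 19 fell and 5 rose (20 and 5 adjusted over the list alone; median -0.66, -0.89 relative to all genes, -0.93 to -0.21 over the alternatives), with a camera adjusted p of 1.4e-06 and an adjusted p = 0.528 with an estimated correlation. gst-4, a reporter of SKN-1 activity, fell from 36.95 ± 6.36 to 9.29 ± 1.42 FPKM, gst-10 from 338 ± 56.2 to 47.04 ± 13.9 FPKM, gstk-1 from 121 ± 17.8 to 19.9 ± 2.55 FPKM and gst-29 from 6.85 ± 2.43 to 1.06 ± 0.0564 FPKM. The rises, chosen after their values were seen, were of gst-12, gst-21, gst-24, gst-41 and gsto-1. Without N2 replicate 3 or mutant replicate 2, 3 rose, without mutant replicate 1 or 3, 2 rose, and after either scaling 3 rose. Of 55 UDP-glucuronosyltransferase genes, 28 fell and 14 rose (29 and 14 adjusted over the list alone; median -0.48, -0.72 relative to all genes, -0.74 to -0.22 over the alternatives), with a camera adjusted p of 8.7e-05 and an adjusted p = 0.528 with an estimated correlation. ugt-6 fell from 80.4 ± 13.8 to 10.1 ± 0.937 FPKM and ugt-47 from 151 ± 18.2 to 30.6 ± 0.831 FPKM, while ugt-18 rose from 0.104 ± 0.0769 to 27.9 ± 4.14 FPKM and ugt-57 from 0.247 ± 0.0920 to 15.7 ± 1.57 FPKM. Without mutant replicates 1, 2 and 3, 7, 9 and 8 rose. Of 47 cytochrome P450 genes, 20 fell and 10 rose (20 and 11 adjusted over the list alone; median -0.08, -0.31 relative to all genes, -0.49 without mutant replicate 3 to -0.0029 without a filter over the alternatives), with a camera adjusted p of 0.00175 and an adjusted p = 0.524 with an estimated correlation. cyp-33C5 fell from 19.8 ± 4.38 to 1.53 ± 0.178 FPKM, cyp-25A1 from 27.5 ± 4.94 to 5.75 ± 0.583 FPKM, cyp-14A2 from 4.53 ± 0.289 to 0.672 ± 0.139 FPKM and cyp-37B1 from 5.38 ± 0.128 to 1.33 ± 0.169 FPKM. With any of the mutant replicates 1, 2 or 3 left out, 6 rose.

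Of 22 SKN-1 and oxidative stress genes, which share gst-4 and gst-10 with the transferase list, 8 fell and 3 rose, also when adjusted over the list alone (median -0.27, -0.51 relative to all genes, -0.53 to -0.20 over the alternatives). The catalase genes ctl-1 and ctl-2 fell 1.97-fold and 2.17-fold, and the superoxide dismutase gene sod-3 rose from 2.09 ± 0.216 to 6.55 ± 1.67 FPKM, as did sod-4 and sdz-8, both chosen after their values were seen. Camera gave an adjusted p of 0.0044, 0.0526 after quantile normalisation (0.000888 to 0.0526 over the other alternatives) and the adjusted p = 0.524 with an estimated correlation. Of 16 DAF-16 activated genes, 7 fell and 4 rose (7 and 5 adjusted over the list alone), with a camera adjusted p of 0.0535, which was 0.0370 both without a filter and with a filter on the mean, 0.0199 without N2 replicate 1, 0.0450 without mutant replicate 2 and 0.524 with an estimated correlation (0.0199 to 0.203 over the other alternatives). ttr-44 fell from 182 ± 31.8 to 44.7 ± 12.9 FPKM, and besides sod-3 the rises, chosen after their values were seen, were of fat-5, asm-2 and lea-1.

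The hsp-16 small heat shock genes were lower. Of 16 cytosolic heat shock genes, 9 fell and 4 rose, also when adjusted over the list alone (median -1.17, -1.404 relative to all genes). hsp-16.1, hsp-16.11, hsp-16.48 and hsp-16.49 fell 3.91-fold to 4.02-fold, hsp-16.1 from 221 ± 37.7 to 55.1 ± 5.07 FPKM. hsp-16.1 and hsp-16.11, and hsp-16.48 and hsp-16.49, are near-identical copies and their separate values are uncertain. hsp-12.3, another small heat shock gene, had a limma adjusted p of 0.595. The rises, chosen like hsp-12.3 after their values were seen, were of the general chaperone genes hsp-1, hsp-90, dnj-12 and dnj-13, and after median-ratio scaling 1 rose. The camera adjusted p was 0.00056, and the adjusted p = 0.524 with an estimated correlation. Among 15 mitochondrial unfolded protein response genes, 1 rose (cyp-14A1) and 2 fell (hsp-60 and K09E9.1), or 1 and 1 adjusted over the list alone, with a camera adjusted p of 0.542. Without N2 replicate 1, 3 rose, and with any of the mutant replicates 1, 2 or 3 left out, 0 rose. The latter was fixed by the filter for cyp-14A1, which was below 1 FPKM in every N2 library and could then not be tested. hsp-6, the mitochondrial HSP70 gene, was at 289 ± 16.53 FPKM in N2 and 277 ± 24.1 FPKM in the mutant (limma adjusted p = 0.656). The gene hsp-60, its partner chaperone, was at 359 ± 15.6 and 291 ± 15.8 FPKM (limma adjusted p = 0.0400). Its limma adjusted p was between 0.0502 and 0.130 when any library was left out and 0.131 with the replicate number as a block. Without a filter it was 0.0375, and after median-ratio scaling it was 0.0068 with a log2 change of -0.57. After quantile normalisation the log2 change was 0.03 in place of -0.30. The gene gpd-2 lay near the filter, at 0.796 ± 0.522 FPKM in N2 and 1.51 ± 0.354 FPKM in the mutant. Its limma adjusted p was 0.0664. Over the alternatives this p was 0.0079 without N2 replicate 1, 0.0336 with the replicate number as a block and up to 0.515. Of 20 endoplasmic reticulum unfolded protein response genes, 7 rose and 0 fell, also when adjusted over the list alone, with a camera adjusted p of 0.322, 0.0137 after quantile normalisation and 0.782 with an estimated correlation (0.0137 to 0.757 over the other alternatives). The share of rises in this list was close to the 4703 of 13576 among all tested genes. hsp-4, the BiP gene, rose from 164 ± 9.23 to 261 ± 14.1 FPKM, dnj-27 from 11.9 ± 1.26 to 35.3 ± 2.38 FPKM and ero-1 from 35.9 ± 0.501 to 61.5 ± 2.71 FPKM. pdi-2 rose from 919 ± 175 to 1435 ± 38.3 FPKM, a call lost after median-ratio scaling, where 3 genes of the list rose and 2 fell.

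Of 32 N-glycosylation genes, 25 did not pass the threshold, 5 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.324). The acetylglucosaminyltransferase genes gly-12 and gly-14 rose 2.48-fold and 2.80-fold and uggt-2 2.59-fold, while the fucosyltransferase gene fut-8 fell 1.88-fold. gly-20 and algn-8 also rose and algn-7 fell, all chosen after their values were seen. The median of 0.02 was 0.05 without N2 replicate 1, -0.07 without N2 replicate 3 and -0.0099 without mutant replicate 1, and it turned to -0.23 after median-ratio scaling, where 3 rose and 10 fell, and to -0.09 after quantile normalisation, where 6 rose and 5 fell. Of 64 cytosolic ribosomal protein genes, 1 rose (rpl-42, from 2.46 ± 0.273 to 4.11 ± 0.911 FPKM) and 0 fell, and none passed when adjusted over the list alone. The call of rpl-42 was lost without N2 replicate 2 or 3 and mutant replicate 1 or 3 and after either scaling. For this list the camera adjusted p was 0.0521, 0.0428 without a filter, 0.00332 without N2 replicate 1, 0.0138 after median-ratio scaling, where 3 fell, and 0.782 with an estimated correlation (0.00332 to 0.917 over the alternatives). rpl-12 was at 1744 ± 142 and 2046 ± 47.9 FPKM, rpl-32 at 1036 ± 183 and 835 ± 83.3 FPKM and rps-19 at 1551 ± 105 and 1340 ± 170 FPKM. The call of rpl-32, absent here, appeared without N2 replicate 3 and after median-ratio scaling.

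Defence genes went both ways. Of 100 C-type lectin genes, 49 rose and 29 fell, also when adjusted over the list alone (camera adjusted p = 0.954), and 28 and 27 rose without mutant replicates 1 and 3. Besides clec-70, clec-71 rose from 0.204 ± 0.110 to 8.06 ± 0.0940 FPKM, clec-17 from 1.102 ± 0.229 to 10.1 ± 0.718 FPKM, and clec-42, at 0 in N2 replicate 2, reached 4.81 to 5.51 FPKM in the mutant. Of 30 lysozyme and saposin-like genes, 14 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.900). The median of 0.25 was 0.04 without mutant replicate 3 and -0.01 after median-ratio scaling. spp-23 rose from 13.2 ± 2.23 to 137 ± 2.20 FPKM, spp-2 from 4.69 ± 1.08 to 37.2 ± 6.04 FPKM and lys-7 from 16.9 ± 6.03 to 91.9 ± 4.10 FPKM. spp-12 was listed at 0 in N2 replicates 1 and 3 and at 0.258 FPKM in N2 replicate 2, and reached 2.68 to 6.97 FPKM in the mutant. Of 31 pathogen and PMK-1 response genes, 12 rose and 11 fell (14 and 11 adjusted over the list alone; camera adjusted p = 0.291), and 7 rose without mutant replicate 1. irg-5 fell from 70.02 ± 9.63 to 14.7 ± 2.32 FPKM and irg-7 from 799 ± 87.3 to 286 ± 11.5 FPKM, while dod-24 rose from 33.9 ± 7.86 to 147 ± 16.3 FPKM. Of 7 intracellular pathogen response genes tested, pals-39, skr-4 and skr-5 rose and skr-3 and cul-6 fell, also when adjusted over the list alone (camera adjusted p = 0.676), cul-6 being chosen after its values were seen. The list median of 0.34 was 0.56 without mutant replicate 2 and -0.02 after quantile normalisation. Of 15 antimicrobial peptide genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.546). abf-6 rose from 0.394 ± 0.279 to 10.2 ± 2.93 FPKM, abf-5 from 0.240 ± 0.118 to 5.56 ± 0.535 FPKM and cnc-3 from 5.91 ± 2.45 to 22.2 ± 4.73 FPKM, and nlp-34 fell from 4.09 ± 1.51 to 0.996 ± 0.174 FPKM. abf-2 and nlp-31 rose and nlp-27 and nlp-29 fell, chosen after their values were seen. With any of the mutant replicates 1, 2 or 3 left out, 2 rose, and 6 and 5 fell after median-ratio scaling and quantile normalisation. Without a mutant library abf-5 and abf-6, below 1 FPKM in every N2 library, no longer passed the filter. Of 13 chitinase and chitinase-like genes, 8 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.542). The count of rises was 4 without mutant replicate 1 and 4 after quantile normalisation. cht-5, cht-1 and cht-2 rose 6.84-fold, 6.29-fold and 4.96-fold. cht-4, and cht-3 and chil-23, both chosen after their values were seen, fell.

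**Figure D3:**
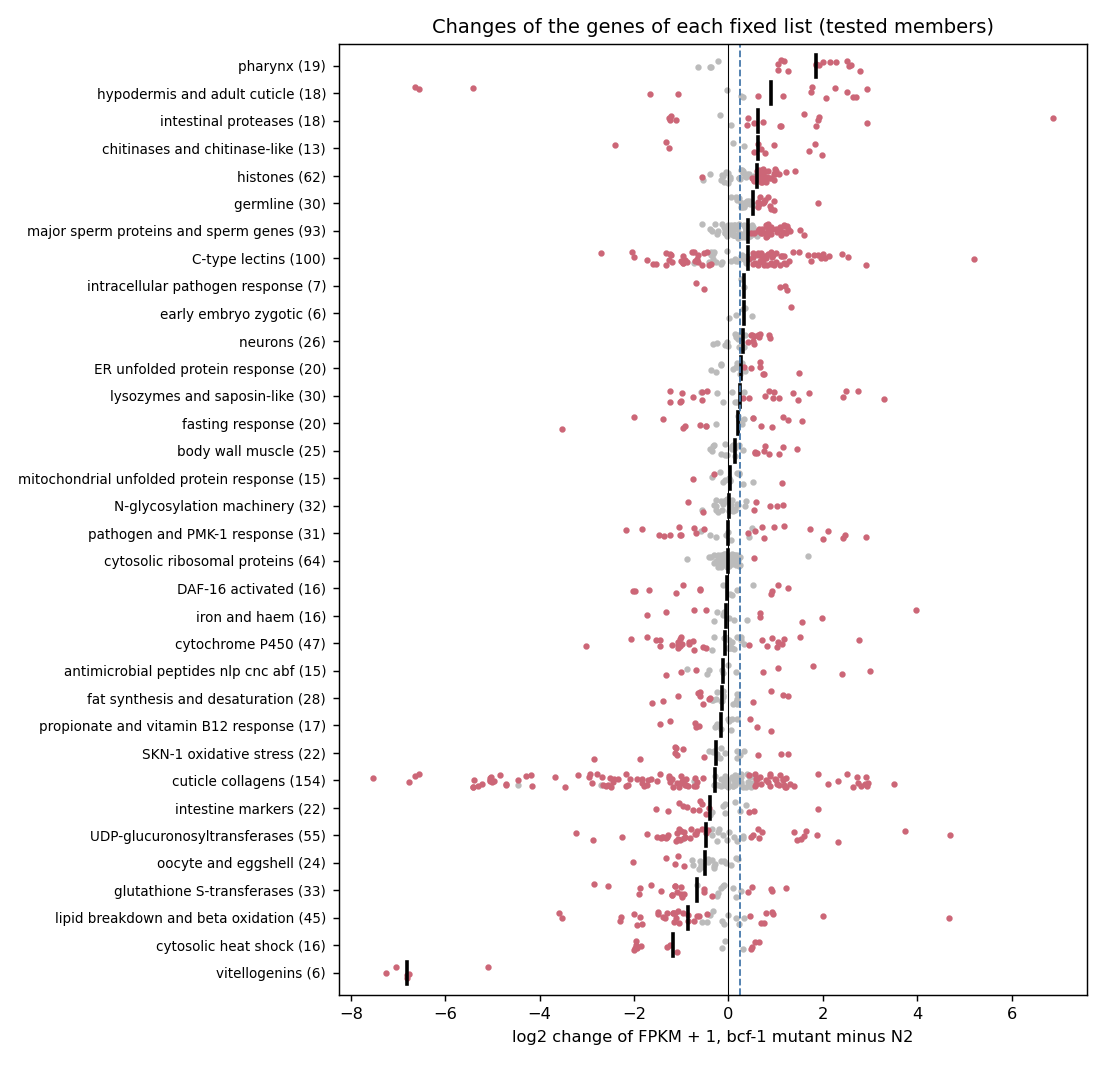
Log2 change of FPKM + 1, bcf-1 mutant minus N2, of each tested member of the 34 fixed lists, with the number tested in parentheses. Red points passed the limma threshold, grey points did not, black bars are list medians and the dashed line is the median of all tested genes, 0.24. List medians run from -6.81 for the vitellogenins to 1.85 for the pharynx genes. The medians of 0.13 for body wall muscle and 0.02 for N-glycosylation turned negative after median-ratio scaling, as did those of the mitochondrial unfolded protein response, fasting response and lysozyme lists, and after quantile normalisation those of N-glycosylation, fasting response, intracellular pathogen response and early embryo genes turned negative and those of iron and haem genes and of cytosolic ribosomal proteins positive. The medians of the N-glycosylation, iron and haem, ribosomal, pathogen response, DAF-16 and antimicrobial peptide lists also changed sign in alternatives other than the scalings.

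In all, camera with the preset correlation called 16 of 34 lists, 4 up and 12 down, and with an estimated correlation it called 0. With an estimated correlation camera tests on the 4 residual degrees of freedom, which limits how small its p-values can be. Among those 16 lists, fry gave adjusted p-values over 0.05 for germline (0.0728), UDP-glucuronosyltransferase (0.0785), propionate (0.122), sperm (0.137) and oocyte genes (0.310). It gave 0.00060 for vitellogenins, 0.0032 for cuticle collagens and pharynx genes, and under 0.05 for the other called lists. Of lists that camera did not call, fry gave 0.0032 for DAF-16 activated and intestinal protease genes. It gave 0.0060 for endoplasmic reticulum unfolded protein response, neuronal, fasting response and early embryo genes, and 0.0066 for C-type lectins. Intracellular pathogen response, antimicrobial, chitinase, hypodermis and muscle lists also lay under 0.05. The other uncalled lists lay over 0.05. Fry does not compare a list with other genes.

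The third comparison asked whether changed genes gathered on any chromosome. On the X chromosome 24.5% of tested genes fell against 13.8% elsewhere (adjusted p = 2.2e-28), whereas 33% rose against 34% elsewhere (adjusted p = 0.509; two-sided Fisher's exact tests throughout). Chromosome V, which carries bcf-1, had 20.1% falling against 14.1% elsewhere (adjusted p = 2.0e-13), while fewer genes fell on chromosomes I (8.79% against 16.52%, adjusted p = 4.5e-22), III (11.04% against 16.02%, adjusted p = 3.1e-09) and IV (13.8% against 15.5%, adjusted p = 0.0390). More genes rose on chromosome IV (37.2% against 33.2%, adjusted p = 0.00114) and fewer on chromosome III (31.4% against 34.3%, adjusted p = 0.0253). Counting rises and falls together, 4 chromosomes differed from the rest, I and III with fewer called genes and V and X with more, and without N2 replicate 1 there were 2. Genes next to each other are often of the same family and are not independent. Among vitellogenin genes, vit-1 to vit-5 lie on the X chromosome and vit-6 on chromosome IV.

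**Figure D4:**
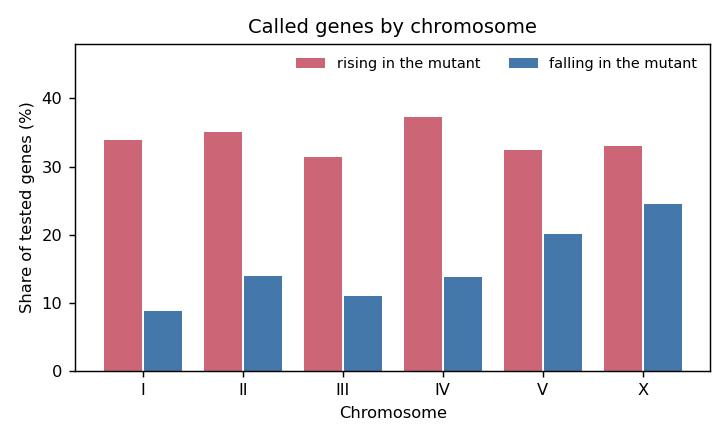
Share of tested genes per chromosome called higher (red) or lower (blue) in the bcf-1 mutant by limma, in percent. The share of falls is 24.5% on the X chromosome and 8.79% on chromosome I.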

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

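Median-ratio scaling and quantile normalisation were chosen after the data were seen. bcf-1 kept its fall in every alternative run, with log2 changes from -2.95 to -2.49. Genes rising in the bcf-1 mutant (4703) were 3041 at a threshold of 0.01 and 3065 after median-ratio scaling, where 3096 fell in place of 2035. Genes rising at least 2-fold (1546) were 1016 after median-ratio scaling and 921 after quantile normalisation. Median-ratio scaling takes the median shift of all genes from 0.24 to 0.0017 and quantile normalisation to 0.072. Of the 6738 calls, 5100 and 5014 kept their call and direction under these scalings, and 0 were called in the opposite direction in any alternative. The gene hsp-60 changed sign after quantile normalisation (0.0315). The number of lists called fell from 16 to 0 with an estimated correlation.

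Leaving out a library gave 4517 to 7590 genes called, 2877 to 5720 rising, 1640 to 1870 falling, 1213 to 1718 rising at least 2-fold, 773 to 964 falling at least 2-fold, 12 to 17 lists, 2 to 5 chromosomes and bcf-1 changes of -2.78 to -2.57. Without a mutant library, genes at 1 FPKM in the mutant only could no longer be tested, so 12982 to 13010 genes entered. Likewise, genes at 1 FPKM in N2 only dropped out without an N2 library, so 13350 to 13374 genes entered. The cuticle collagen list then held 146 or 147 tested genes in place of 154, and the vitellogenin list 5 in place of 6. Replicate numbers did not pair the libraries: deviations of equally numbered libraries correlated at 0.0097, -0.07 and -0.28, and no library correlated best with its own number. With the replicate number as a block 6172 genes were called and 6009 of the 6738 calls remained. The filter planned as stricter tested 13446 genes. Tests and normalisations that need counts were not run, because the table holds none. Depth is unknown, so its limit on low genes could not be set.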

Other observations

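The tests of gene families, collagens, scaling, intestine markers and shared reads were chosen after the results were seen, and those of moulting genes, of genes near the locus and of other splits before, though the moulting list was written once other changes were known. Gene families named by a shared symbol prefix were tested with camera, 128 families with at least 10 tested members. With the preset correlation 28 passed, 9 higher and 19 lower, and with an estimated correlation 0 did. Carboxylesterase genes (cest) fell in 17 of 27 cases and rose in 2, with cest-10 at 26.8 ± 4.24 FPKM in N2 and 6.49 ± 0.754 FPKM in the mutant (SD, n = 3). Peroxisome assembly genes (prx) fell in 9 of 11 cases, led by prx-3, from 41.6 ± 5.77 to 16.6 ± 0.687 FPKM. Galectin genes (lec) fell in 8 of 12 cases and rose in 1, with lec-9 at 367 ± 46.7 and 166 ± 10.3 FPKM. Transthyretin-like genes (ttr) fell in 26 of 51 cases and rose in 13 (8, 8 and 7 without mutant replicates 1, 2 and 3), and ttr-46 dropped from 558 ± 47.1 to 117 ± 6.09 FPKM. These falls outnumbered the rises after both scalings too.

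Other families were higher. In the nspc family of small nematode-specific peptides 16 of 18 genes rose, nspc-12 from 3.45 ± 0.747 to 27.2 ± 2.48 FPKM, although close copies leave single values uncertain. Insulin-like peptide genes (ins) rose in 12 of 15 cases, ins-4 from 0.688 ± 0.260 to 4.22 ± 0.696 FPKM, and in 7 of 10 tested with any of the mutant replicates 1, 2 or 3 left out, with 1 fall after either scaling. Neprilysin-like genes (nep) rose in 15 of 21 cases and fell in 2, nep-1 from 20.5 ± 3.06 to 71.9 ± 12.1 FPKM. Of 117 col genes, 72 fell and 12 rose, while of 24 dpy genes, which are named for a body shape and only partly encode collagens, 18 rose and 0 fell. The mitochondrial ribosomal protein genes (mrpl) fell in 7 of 42 cases, in 28 after median-ratio scaling, 14 after quantile normalisation and 1 to 4 when any library was left out.

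A first pattern is that the vitellogenins and many collagen genes fell while moulting and apical matrix genes, made before each larval moult, rose in 25 of 38 cases and fell in 6, with a median of 1.35 (camera p = 0.0041, and p = 0.426 with an estimated correlation), noah-1 from 44.9 ± 13.9 to 210 ± 9.58 FPKM. A candidate explanation is that the mutant cultures were at an earlier stage than the N2 cultures, by slower growth or by the time of collection. The design cannot separate these, and no staged library was analysed here. Oocyte and major sperm protein genes moved less. Of 24 oocyte and eggshell genes, 5 fell and 19 were not called, and of 30 msp genes 3 rose and 0 fell. Median-ratio scaling applies 1 factor per library and took the median of all genes from 0.24 to 0.0017. Such a shift could not undo the vitellogenin fall, so their median of -7.03 after it does not test scaling. The moulting list kept medians of 1.098 after median-ratio scaling (24 rose, 7 fell) and 1.18 after quantile normalisation (24 rose, 6 fell). The vitellogenin median was -6.89 after the latter, and such opposite changes argue against scaling as the source of both. A loss limited to the intestine is argued against by the cuticle collagen list, whose collagens are made mainly in the hypodermis. Of this list 46.8% fell against 14.6% of other genes, a count with no independent test behind it (camera adjusted p = 0.524 with an estimated correlation). That share replaced a first test on col-7, col-19, col-62 and col-63, which left the question undecided at a median of -5.98, because it asked for all 4 to be separated between the genotypes and col-63 stood at 726 ± 203 and 717 ± 192 FPKM, and the counts behind the share were known when it was chosen. Of the 10 splits of the 6 libraries into 3 and 3, the real split called 6738 genes and the highest other 1, which are too few splits for a share under 0.05.

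A second pattern is that bcf-1 and gfi-1 fell together. Intestine markers had a median of -0.40 against -2.69 for bcf-1, which argues against a lower share of intestinal RNA as the whole source, and the median of -0.0097 within 100 kb, with 7 genes higher, 5 lower and the largest fall that of alh-4 (-1.80), argues against an equal fall of the whole region. The mean ratio of gfi-1 to bcf-1 was 1.03 ± 0.0158 in N2 and 1.13 ± 0.0193 in the mutant, without overlap, so it was near 1 but not the same in both, which leaves open whether reads of these similar genes were divided between them. If they were, the fall of gfi-1 could come from bcf-1, and the separate changes cannot be told apart without the reads. Whether bcf-1 itself changes with stage was not tested, so its fall may come from the allele, from stage or from both.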
